A study of Brassica oleracea var. italica with 2 samples.

How the data were processed

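Expression was measured in 2 samples of broccoli seedlings, 1 with an empty vector and 1 with a BoEMF2.1 antisense construct. Per the labels' protocols, seedlings grew for 11 days on plates of 0.8% agar with reduced-strength MS medium and 1.5% sucrose, at 21 °C with 16 h of light and 8 h of darkness. RNA was extracted with Trizol, and 10 µg of total RNA was used to make biotin-labelled cRNA by the Affymetrix protocol. Groups were taken from the sample titles. For the antisense sample the title gives the prefix "as" and the source name says antisense. Its genotype label names the 35S construct without that word, and the title and source name were followed. The arrays carry Arabidopsis probe sets, so broccoli transcripts were measured by hybridization across species: a low signal can reflect sequence differences from Arabidopsis as well as low expression, and ratios between arrays compare the same probe set only.

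The deposited values are intensity values on a linear scale, 1 per probe set and array, and MAS5 is named in the submitters' processing notes, with no version given in the sources used here. The trimmed mean, leaving out 2% at each end, was 499.838 on the vector array and 499.834 on the antisense array, which shows a common scaling. Detection calls and scanner files were not used here. The 10th and 90th percentiles of the signal were 35.4 and 1261.66 on the vector array and 32.6 and 1280.41 on the antisense array, and the 10 brightest probe sets held 7.05% and 6.72% of the summed signal.

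Of 22810 probe sets, the annotation table used here gives 1 gene for 13513, several for 503 and none for 8794, 64 of them array controls. Genes were named only from probe sets with 1 gene, in the symbols of that table. Values below each array's median over 22746 non-control probe sets were raised to that floor. A ratio was taken as log2 of antisense over vector signal, as a bound where 1 array was below the floor, and not taken where both were. As the floors differ, a bound near 0 can have the opposite sign to the signals themselves. The named genes were the 12 highest and 12 lowest ratios among single-gene probe sets above the floor on both arrays, the 6 largest bounds each way, and in each gene list members past 2-fold, which may be named, and otherwise up to 4 with the largest ratios. For a few lists, members with smaller ratios are also given, to show the range (among them atpB, atpE, psbA, rbcL and SBPASE), chosen after their values were seen. Floor, threshold, named-gene rule and 17 gene lists were set before the data were examined.

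The 17 preset lists hold 296 entries, of which 36 were matched, 2 by locus code and 34 by symbol. Matching by locus code alone had been planned, but the table gives a symbol in place of the locus where it has one, so symbols were matched and the table's gene numbers were checked against the chromosome of the locus. The symbol CHI is also in use for chalcone isomerase. It was taken for a chitinase gene because its gene number in the table falls between those of AT2G43560 and AT2G43580. Because few entries matched, 32 further lists were made from the table's gene names after the names but before any ratio was seen. A list with at least 3 measured members was described by its median and the percentile of that median among 10000 random lists of the same size, matched on mean signal in 10 bins. With several probe sets for a gene, the brightest was used. With 1 sample per group no p-value was computed, and percentiles describe these 2 arrays.

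The spread of a single ratio was estimated from 31 genes with 2 probe sets above the floor on both arrays. Probe sets were paired by gene name alone, so different genes that share a symbol could be paired. The procedure was tested on simulated data for this comparison, over 22746 probe sets with noise between probe sets only: 99.5% of 200 probe sets shifted by a log2 of 2 were recovered and 174 of 10301 unshifted ones passed 2-fold. The shifted ones were drawn from bright probe sets alone and moved well past the threshold. Recovery of smaller shifts, or near the floor, was not tested. Alternatives were centring, quantile normalization, loess on brightness with a span of 0.4, floors at the 25th and 75th percentile or none, a pseudocount at the 25th percentile, thresholds of 1.5-fold and 3-fold, other choices of probe sets and list members, and, added after seeing the data, scaling to the hybridization controls, leaving out plastid-encoded genes, and narrowing the list of histone, replication and mitosis genes and that of TRM genes. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.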

Results

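The data were MAS5 signal intensities from 2 oligonucleotide arrays carrying 22810 Arabidopsis probe sets, each hybridised with labelled RNA from whole broccoli seedlings of the cultivar Elegance. One array held seedlings with an empty binary vector, pCAMBIA1380, and the other held seedlings expressing an antisense copy of BoEMF2.1 from the 35S promoter. BoEMF2.1 is a broccoli relative of the Arabidopsis gene EMF2, which encodes a Polycomb group protein that represses flower development genes. Seedlings were 11 days old and had grown in 16 h of light and 8 h of darkness. There was 1 sample per group, so no value has a replicate error, no difference between the genotypes was tested, and "higher" and "lower" describe these 2 arrays alone. The number of arrays limits the precision of every ratio. The median signal was 318.25 on the vector array and 303.15 on the antisense array, and the maximum was 182426 and 183316. Across probe sets, which are not replicates, the log2 signals correlated with Pearson's r = 0.832, and with r = 0.902 among probe sets above the floor on both arrays. The floor was each array's median over non-control probe sets, 317.6 and 302.7. The annotation used here names no probe set for EMF2, VRN2, FIS2, EMF1, CLF, SWN, FIE or MSI1, so the level of the targeted gene, which would check the labels, was not analysed here. No chromosome coordinates of probe sets were used here.

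The comparison of the antisense with the vector array asks which transcripts differ in seedlings carrying the BoEMF2.1 antisense construct. Genes encoded in the plastid genome were lower in the antisense array, nearly as a whole. Among nuclear genes, the chitinase gene AT2G43620 had the highest ratio of any named gene measured on both arrays, at 10.1-fold. The chitinase gene CHI was at least 24.13-fold higher. Of the preset flowering genes, few could be measured, and these lay between -0.31 and 0.23 on the log2 scale except SMZ, an AP2-type repressor of flowering, which was at least 2.78-fold lower. Ratios below are log2 of antisense over vector signal unless a fold is given, and "at least" marks a bound, for a gene under the floor on one array.

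Of 9382 probe sets above the floor on both arrays, 283 (3.02%) were 2-fold or more higher in the antisense array and 329 (3.51%) were 2-fold or more lower. Of the 3975 above the floor on one array, 175 were higher and 228 lower by a bound of 2-fold or more, and 9389 were below the floor on both. With the arrays scaled to the hybridization controls instead of to the trimmed mean, a choice made after seeing the data, the median over the 9382 probe sets above the floor on both arrays shifted from -0.02 to -0.22. The split then went from 283 higher and 329 lower (46.24% higher) to 154 higher and 585 lower (20.84% higher). Positive ratios under 0.19 given here turn negative under that scaling, while list percentiles, which are relative to other probe sets, do not move. The ratios had an SD of 0.54 across probe sets. The SD of a single ratio, from 31 gene names with 2 probe sets each, was 0.43. It covers probe noise within these arrays, and any difference between genes that share a name, and not variation between plants. Simulated noise of that size alone gave on average 192 probe sets past 2-fold, against 612 observed, and a spread of 0.30 from the median absolute deviation gave 8.80.

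**Figure D1:**
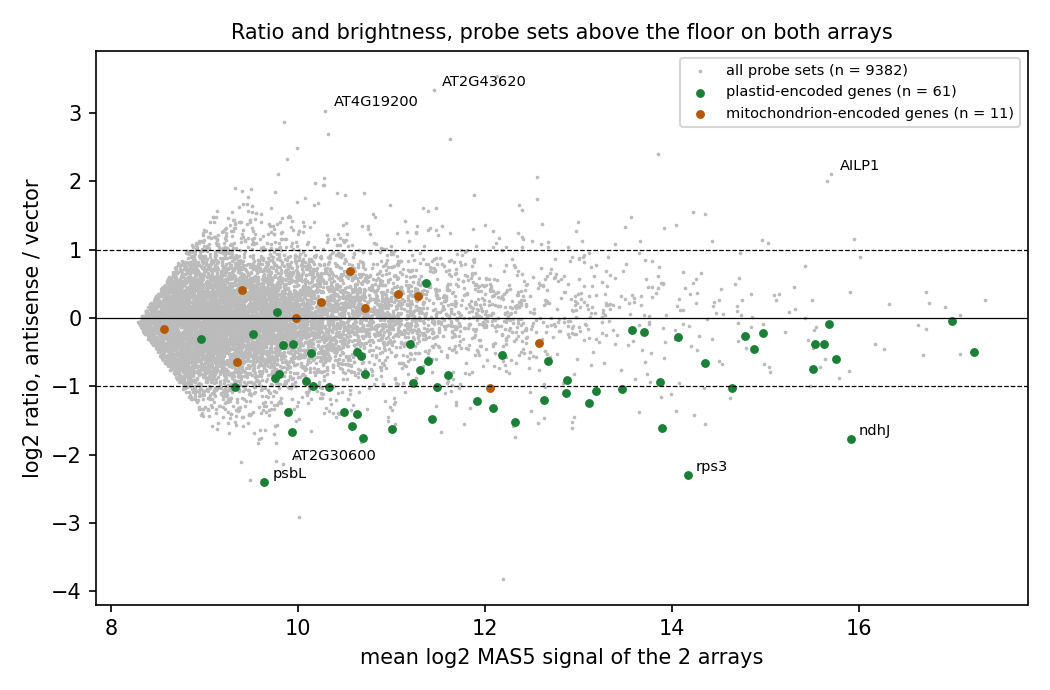
Log2 ratio of antisense over vector signal (y axis) against the mean log2 MAS5 signal of the 2 arrays (x axis) for the 9382 probe sets above the floor on both arrays, in grey, with plastid-encoded genes in green and mitochondrion-encoded genes in orange. Dashed lines mark 2-fold; plastid-encoded genes lie mostly below 0, with psbL at -2.40, and AT2G43620 lies highest of the labelled genes at 3.33.

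Among named genes measured on both arrays, AT2G43620 had a signal of 882.5 on the vector array and 8882.8 on the antisense array. AT4G19200 followed at 8.20-fold higher (436.9 and 3582) and AT5G60800 at 6.47-fold higher (501.9 and 3247.8). AILP1 was 4.31-fold higher, at 25693.2 and 110787. AT1G76590 was 4.31-fold, AT3G52360 4.15-fold, AT3G15810 3.94-fold and FMO 3.86-fold higher. LSM3B, an Sm-like protein of RNA processing, was 3.63-fold higher, AT1G56060 was 3.60-fold and AT5G49540 3.49-fold higher. PDF1.4, a defensin, was 3.24-fold higher, at 563.5 and 1828.1. By bound, CHI led, with signals of 73.8 and 7664, then BGLU27, a beta-glucosidase, at least 5.78-fold higher, AT2G34050 at least 5.03-fold, AT4G17480 at least 4.50-fold, AT1G23440 at least 4.096-fold, and the alpha-amylase AMY1 at least 4.06-fold higher.

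At the other end, psbL, a small subunit of photosystem II encoded in the plastid, was 5.27-fold lower (1821.8 on the vector array and 345.4 on the antisense array). Both probe sets of AT2G30600 were lower, by 5.16-fold and 4.38-fold. The plastid ribosomal protein gene rps3 was 4.92-fold lower, at 40757.2 and 8281.1. AT5G51260 was 4.29-fold, AT3G32270 3.56-fold, AT1G16080 3.43-fold, AT5G52820 3.37-fold and AT3G27770 3.24-fold lower. The other members of the lowest 12 were plastid-encoded as well: ndhJ was 3.41-fold lower (113534 and 33295.9), rpl36 3.37-fold and ndhE 3.17-fold lower. By bound, AT1G32120 was at least 4.67-fold lower, AT1G60610 at least 4.06-fold, AT5G12890 at least 4.04-fold, AT3G21770 at least 3.70-fold, CYB-1 at least 3.59-fold and ARLA1C at least 3.53-fold lower. Probe sets without a gene name included some of the widest ratios. Of these, the highest ratio was 11.6-fold (1312.5 and 15250.5), followed by 7.29-fold, and the lowest was 14.2-fold lower (17609.8 and 1243.4), followed by 7.52-fold lower.

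Plastid-encoded genes were lower as a group. Of 67 genes in the plastid lists, 65 were above the floor on at least 1 array, and their median ratio was -0.82 (mean -0.83, SD over genes 0.57). By their own signals 62 were lower and 3 higher in the antisense array, 24 genes were 2-fold or more lower and 0 were 2-fold or more higher. None of 10000 random lists of the same size and signal had a median as low. Random lists draw genes as if independent, which genes of the same plastid genome may not be. Percentiles of the plastid lists may therefore be too extreme. The 3 higher genes were rps15 at 0.51, petD at 0.09, which is negative under scaling to the hybridization controls, and atpF (272.2 and 305.5), close to the floor. These 24 genes were among 169 single-gene probe sets that were 2-fold or more lower. The arrays also differed in plant control probe sets for the ends of a transcript: in 4 of 5 pairs measured on both arrays the ratio was higher at the 5′ than at the 3′ end, with differences from -0.34 to 0.62 and a median of 0.44. The pairs are not independent, as they cover actin (0.62 and 0.04), ubiquitin (0.52 and 0.44) and GAPDH (-0.34) alone. Control sets for the Bacillus gene dap went both ways, with ratios of 0.23 (5′) and 0.04 (3′), and of -0.87 and 0.14. Of the root marker genes, EXPA7 and EXPA18 were higher in the antisense array, at 1.63 and 0.80, and PYK10 was lower, at -0.44.

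The plastid genes for photosynthesis, 35 in number, had a median of -0.71, with 11 of them 2-fold or more lower. Next to psbL, psbF stood at -1.62, psbH at -1.58, ycf3, an assembly factor of photosystem I, at -1.48, and psaA, a core protein of photosystem I, at -1.37. The gene for the large subunit of Rubisco, rbcL, stood at -0.66 (26292 and 16589.1), psbA at -0.38, and the ATP synthase genes atpB and atpE at -0.50 and -0.05. The 9 measured genes of the plastid NDH complex were all negative, with a median of -0.63, at percentile 0.105 of random lists, and 4 were 2-fold or more lower. The 21 genes in the list of plastid gene expression had a median of -0.86, with 9 of them 2-fold or more lower. That list also held accD (-0.17) and clpP (-0.59), which do not act in gene expression. Its 2-fold lower members included the ribosomal protein genes rpl33 at -1.61 and rps19 at -1.52, and the RNA polymerase genes rpoA and rpoB, both at -1.01. Centring took rpoA and rpoB under 2-fold (both -0.99), as did quantile and loess normalization for rpoB (-0.98 and -0.97).

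The medians for genes of the other organelle genome and for nuclear genes for chloroplast proteins did not show a shift of that size. The 13 measured mitochondrion-encoded genes had a median of 0.15, at percentile 83.9, which became -0.05 with hybridization-control scaling, and 1 of them, nad4, was 2-fold or more lower (-1.02), though not after centring on the median (-0.998). The 27 measured nuclear genes for photosynthesis and chlorophyll had a median of -0.07, at percentile 21.5, with 17 lower and 10 higher by their own signals. Of these, 1 was 2-fold or more lower, PSAN, a photosystem I subunit, at -1.52 (13222.1 and 4622.5). PORB, an enzyme of chlorophyll synthesis, stood at -0.96 and PSAE-1 at -0.82, while RCA, which activates Rubisco, stood at 0.64 and SBPASE at 0.37. The light-harvesting and photosystem subunit genes of this list were all lower, from -0.02 (PSBW) to -1.52 (PSAN). In the photosynthesis list fixed before the data were examined, 4 of 30 genes were measured (PSAN, LHCB4.1 at -0.05, PRK at 0.14 and RCA), with a median of 0.04 at percentile 47.8. That median turned negative with quantile, loess and hybridization-control scaling, to -0.03, -0.04 and -0.15.

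**Figure D2:**
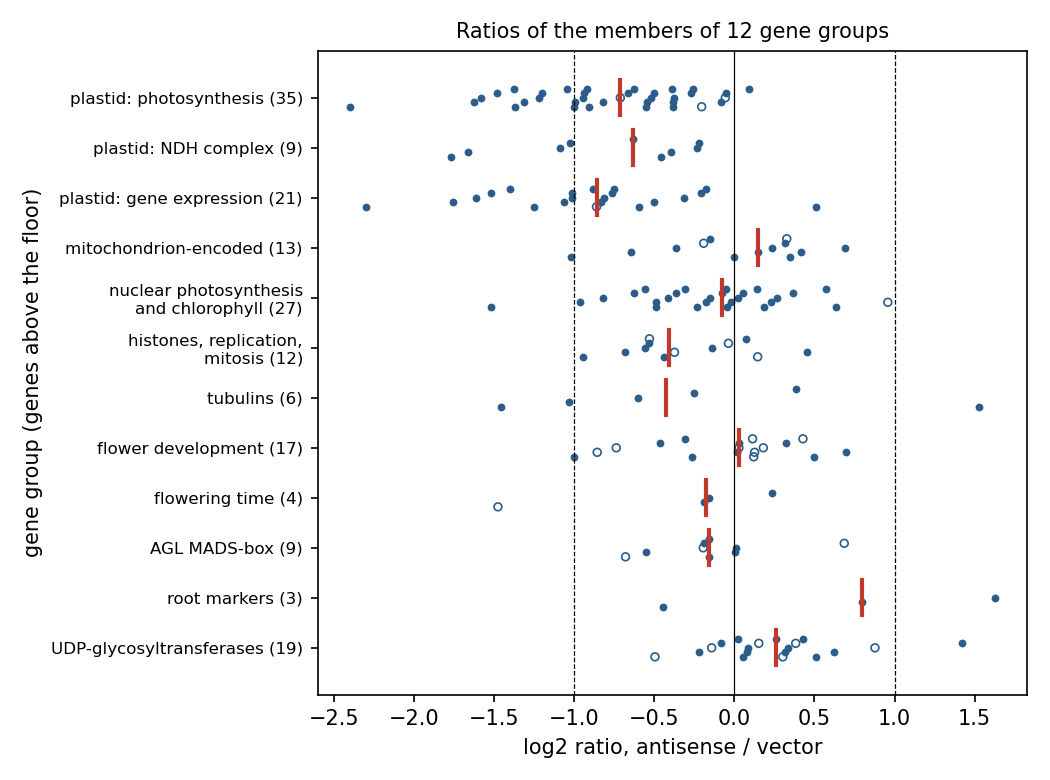
Log2 ratio of antisense over vector signal (x axis) of each measured member of 12 gene groups (y axis, number of genes in brackets), chosen for display after the values were seen; filled points are above the floor on both arrays, open points are bounds, and red bars are group medians. The 3 plastid groups have medians of -0.71, -0.63 and -0.86, against -0.07 for nuclear photosynthesis genes and 0.15 for mitochondrion-encoded genes, the latter -0.05 with hybridization-control scaling.

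Flowering genes were thinly covered. Of 30 flowering time genes, 7 were matched and 4 measured, with a median of -0.17 at percentile 31.6. SMZ had signals of 841.3 and 262.5, a bound of -1.47. AGL24 stood at -0.19, AGL19 at -0.16 and GI, also in the circadian clock list as its single measured member, at 0.23 (1334.9 and 1569.9). AGL42, FD and LD were below the floor on both arrays. Among floral organ identity and floral meristem genes, 2 of 23 were measured, SPT at -0.31 (535.4 and 433.3) and UFO at 0.03 as a bound (240.1 and 324), and JAG and SPL were below the floor. FLC, FT, SOC1, AG, AP1, AP3, PI and SEP3 were not named in the annotation and were not analysed here. Of the Polycomb and chromatin regulators, ULT1, a trithorax group factor, was measured, at 0.22 (434.2 and 504.5). A broader group of flower, anther and ovule development genes had 17 measured members and a median of 0.03 at percentile 82.3, or -0.16 with hybridization-control scaling. In it, 1 gene was 2-fold or more lower, ROXY2, a glutaredoxin of anther development, at -1.003 (889.2 and 443.6), which was under 2-fold after centring, quantile or loess normalization (-0.98, -0.97 and -0.96). Of 40 AGAMOUS-LIKE MADS-box genes, 9 were measured, with a median of -0.16 at percentile 30.8 and 0 past 2-fold either way.

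Among lists for tissue makeup and growth, the 3 measured root marker genes had a median of 0.80 at percentile 98.045. EXPA7 and EXPA18, expansins of root hairs, stood at 1.63 (374.7 and 1158.2) and 0.80 (1127.5 and 1959), and PYK10, a root beta-glucosidase, at -0.44. A list of histone, DNA replication and mitosis genes had a median of -0.41 over 12 measured members, at percentile 1.70, with 0 past 2-fold. It rested on 3 mitotic kinase and spindle checkpoint genes, AUR1 at -0.68, AUR3 at -0.56 and BUB3.1 at -0.53 as a bound. The 9 histone and replication genes, 5 lower and 4 higher by their own signals, had a median of -0.14 at percentile 32.4, with HTB1, a histone H2B, at -0.95. The 6 measured tubulin genes went both ways around a median of -0.43, at percentile 2.91. TUB7 stood at -1.45 (13077.7 and 4774) and TUB6 at -1.03, while TUA1 stood at 1.52 (456.4 and 1312.3). Of 19 measured UDP-glycosyltransferases, enzymes that attach sugars to small molecules, 15 were positive, with a median of 0.26 at percentile 97.51, and UGT74D1 stood at 1.42. Among 31 lists of genes not encoded in the plastid, these were 3 outside the central 95% of random lists (root markers, UDP-glycosyltransferases, and histones with mitosis genes), where chance alone would give 1.55. With no floor the percentile of UDP-glycosyltransferases was 85.5, inside the central 95%.

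The remaining lists fixed before the data were examined held few measured genes. Cold and abscisic acid response genes had LTI30 at -0.44 as a bound and COR15B at 0.08, with COR15A and COR47 below the floor. The heat shock gene ATHSP22.0 stood at -0.30. Of glucosinolate genes, UGT74B1 stood at 0.43 and BCAT4 at 0.71 as a bound, and of flavonoid genes DFR stood at -0.10 and UGT78D2 at -0.14 as a bound. PDF1.2, the single matched defence and wound response gene, was below the floor (88.7 and 170.9), as were CLV3 in the meristem list and GID1A, IAA29 and GH3.3 in the gibberellin and auxin list. No seed maturation, cell cycle or senescence gene was matched. Of the reference genes, 2 were measured, AT2G28390 at -0.10 (700.7 and 655.3) and AT4G34270 at 0.95 as a bound (215.8 and 615.3). Over the preset lists, 35 distinct genes were matched and 23 measured, of which 1 was 2-fold or more higher (EXPA7) and 2 were 2-fold or more lower (SMZ and PSAN).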

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

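The comparison below was chosen after the values were seen. Among plant control probe sets, 3, which lie outside the comparison of genes, had higher antisense-to-vector log2 ratios than any of the 18 hybridization controls, whose highest was 0.56. They were the GAPDH 5′ probe set at 0.63, the ubiquitin 5′ probe set at 0.61, and a second ubiquitin 5′ probe set at 0.86. All 3 lie at 5′ ends. The ratios at the matching 3′ ends were 0.10 for the first ubiquitin control and 0.42 for the second, and the 3′ GAPDH probe set was below the floor on both arrays, while the middle one stood at -0.37. In other pairs, actin stood at -0.16 (5′) and -0.78 (3′), a second actin set at -0.24 and -0.29, and a second GAPDH set at -0.01 and 0.33, so that 5′ exceeded 3′ in 4 of 5 pairs. These pairs cover actin, ubiquitin and GAPDH alone, and GAPDH went the other way. Middle probe sets of ubiquitin (-0.15) and the second actin set (-0.50) lay below both ends, that of the first actin (-0.73) between them. Bacillus dap controls went both ways, at 0.23 (5′) and 0.04 (3′), and at -0.87 and 0.14. A Bacillus thr 5′ control fell from 422.2 to 15.7, below the floor, against 0.81 at its 3′ end. With hybridization-control scaling the 3 flagged 5′ ratios would be lower by 0.19, the median of the hybridization controls. The 16 plant controls above the floor on both arrays ranged from -0.78 to 0.86 around a median of -0.08.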

How the results depend on the processing

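Scaling to the hybridization controls, leaving out plastid-encoded genes and narrowing the mitosis and TRM lists were chosen after seeing the data. No paired analysis was possible because each group holds 1 sample, and no sample could be left out. The alternatives planned for EMF2 were not run, as no probe set is named for it. Counts of probe sets depended by construction on the floor, which sets how many dim probe sets enter, and on the fold threshold. Probe sets above the floor on both arrays and 2-fold higher or lower, 283 and 329, became 1149 and 1352 with the floor at the 25th percentile, 114 and 111 with the 75th, 3241 and 3691 with no floor, and 1463 and 1879 with a pseudocount. They became 154 and 585 with hybridization-control scaling, 1085 and 1229 at 1.5-fold, 40 and 30 at 3-fold, and 144 and 169 with single-gene probe sets alone. Bounds past 2-fold, 175 higher and 228 lower, became 943 and 1083 with the 25th percentile floor, 53 and 47 with the 75th, 93 and 413 with hybridization-control scaling, 535 and 717 at 1.5-fold, 30 and 37 at 3-fold, and 85 and 120 with single-gene probe sets. The spread of a ratio, 0.43, became 0.911 with the 25th percentile floor, 1.33 with no floor and 0.765 with a pseudocount; the cause was not tested. The floor, set at each array's median without regard to background, left 9389 probe sets below it on both arrays, with no ratio. The midpoint of the 2 reference genes, 0.43, became -0.10 with the 75th percentile floor or with members above the floor on both arrays alone, since 1 gene was then left. The plastid-encoded median ranged from -1.01 to -0.80 over 11 alternatives, with 21 to 34 genes 2-fold lower, and lay below all random lists in each. Percentiles ranged from 98.005 to 99.51 for root markers, 1.37 to 32.4 for the histone, replication and mitosis list, the highest without its mitotic kinase and checkpoint genes, and 85.5 to 98.6 for UDP-glycosyltransferases. Hybridization-control scaling turned the sign of 13 list medians, loess 4, quantile normalization 3 and centring 1. Of 85 named ratios or bounds past 2-fold, 33 higher and 52 lower, hybridization-control scaling took 8 under 2-fold, all higher ones, centring took 5, all lower ones, and quantile and loess normalization 4 each, with 1 higher and 3 lower. Of 105 named results, 41 moved by more than the spread and 54 did not with the 75th percentile floor, where the rest had no value, 14 moved with the 25th, 14 with no floor and 7 with a pseudocount.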

Other observations

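The tests on plastid-encoded genes were chosen after their ratios were seen. The chitinase and branched-chain amino acid lists were made after their leading members had been seen, with the tests set before the other members were looked at.

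Several gene families not described so far held members past 2-fold in the antisense array. Of 12 measured beta-glucosidases (median 0.05, percentile 69.9, or -0.14 with hybridization-control scaling), BGLU27 and BGLU40 (1.08) were higher. Of 28 measured expansin, XTH and GH9 cell wall genes (median -0.08, percentile 36.9, 0.01 with loess), EXPA7 and XTH33 (a bound of 1.08) were higher, and EXPA8 (a bound of -1.80), XTH32 (-1.34) and GH9B13 (-1.03) were lower. Of 7 measured defensin-like and RALF-like peptide genes (median 0.30, percentile 88.6), PDF1.4 and RALFL22 (1.097) were higher. A list of defence and senescence genes held regulators and also other genes, such as the chitinases CHI and ChiC. Of its 15 measured members (median 0.21, percentile 93.0), CHI and OSM34 (a bound of 1.01) were higher and PUB23, a ubiquitin ligase, was lower (-1.03). The 5 measured U-box ubiquitin ligases had a median of -0.41 (percentile 9.68), with PUB19 at least 2.65-fold lower and PUB23 lower. All 10 measured ubiquitin conjugating enzymes were positive with the deposited scaling, with a median of 0.32 (percentile 95.3). A list of cold-regulated, LEA and other genes had 5 measured members (median 0.08, percentile 66.2, -0.11 with hybridization-control scaling). Of these, XERICO, which is neither a COR nor a LEA gene, was higher (1.399). With hybridization-control scaling BGLU40 (0.89), XTH33 (0.88), RALFL22 (0.90) and OSM34 (0.82) were under 2-fold, as was GH9B13 with quantile or loess normalization (-0.99 and -0.96).

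The 9 measured TRM genes had a median of 0.36 (percentile 97.4), with TRM15 (1.55) and TRM19 (1.07) higher and TRM21 lower (-1.16), and the median was -0.10 with the floor at the 25th percentile. Without TRM82, which shares only its symbol with the others, the median of the 8 was 0.13 (percentile 78.0). The 11 measured SWEET sugar transporters had a median of 0.31 (percentile 97.0) and 0 members past 2-fold. The other lists had percentiles between 34.9 and 83.0, and some held members past 2-fold. Higher were the tetraspanin TET8 (1.24), the carboxypeptidase-like SCPL49 (1.05) and, as bounds, TBL23 (1.35), UBP22 (1.03) and IQD19 (1.03). Lower were CYP71B22 (-1.395), scpl25 (-1.23) and TBL18 (-1.18). With hybridization-control scaling TRM19 (0.88), SCPL49 (0.86), UBP22 (0.84) and IQD19 (0.83) were under 2-fold, and SCPL49 also with quantile (0.997) or loess normalization (0.99). The medians of these lists were -0.10 for glutathione S-transferases, -0.09 for serine carboxypeptidase-like genes, -0.08 for trichome birefringence-like genes and -0.03 for bZIP factors, the last turning to 0.01 with quantile or loess normalization. Medians were 0.04 for tetraspanins, 0.08 for CYP71B cytochromes P450, 0.01 for IQD genes, 0.01 for WRKY factors, 0.13 for ATG8 and APG8 autophagy genes, 0.13 for VPS and SNF7 genes and 0.15 for calmodulin-like genes, each turning negative with hybridization-control scaling. The median of ubiquitin proteases was -0.00027, turning to 0.06 with quantile normalization. FMA, the single measured stomatal lineage gene, stood at 0.07, or -0.13 with that scaling.

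Plastid-encoded transcripts were lower in the antisense array (median -0.82 over 65 genes), where 3 root markers also stood at 1.63 (EXPA7), 0.80 (EXPA18) and -0.44 (PYK10), with their median at percentile 98.045. Less green tissue, as with a larger share of root, would lower nuclear photosynthesis genes alike. Their median lay 0.745 above (95% bootstrap interval over genes 0.397 to 0.946), which argues against it as the whole cause. Their light-harvesting and photosystem subunit genes were all lower, from -0.02 (PSBW) to -1.52 (PSAN), so a part from less green tissue stays open. A poorer yield of organelle transcripts in labelling would lower mitochondrion-encoded genes, whose median lay 0.965 above (0.482 to 1.24). These intervals resample genes of 2 arrays as if independent, so they may be too narrow and do not cover variation between plants. A trend with brightness would go with loess, after which the median was -0.84. The hypothesis that transcription by the plastid-encoded polymerase alone may be lower was left open: genes read mainly by the nuclear-encoded polymerase (rpoB, rpoC1, rpoC2, accD and clpP) had a median of -0.59 against -0.71 for photosynthesis genes, a difference of 0.118 (-0.348 to 0.644), and the 2 classes cannot be told apart with 5 genes in one of them. With 1 sample per genotype, the antisense construct, a difference between seedling batches and a different share of plastid RNA in the 2 extracts stay open. So does a difference in RNA integrity or labelling. Plant control ratios were higher at the 5′ than at the 3′ end in 4 of 5 pairs, from actin, ubiquitin and GAPDH alone. Control sets for the Bacillus gene dap went both ways (5′ 0.23 and 3′ 0.04, and 5′ -0.87 and 3′ 0.14). The controls thus show no uniform difference between ends.

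A second hypothesis is that chitinase family genes were higher in the antisense array as a family. Of 8 measured members (median 1.26), 4 were 2-fold or more higher: AT2G43620 (3.33), CHI, AT2G43590 (at least 3.90-fold) and AT4G01700 (1.56). The 4 measured members not looked at before had a median of 0.57, at percentile 98.89 of random lists. They were AT2G43610 at 0.95 (9175.4 and 17786.4), AT2G43580 at 0.86 as a bound, ChiC at 0.28 and AT3G47540 at -0.19 as a bound. By locus code AT2G43610 and AT2G43580 are neighbours of AT2G43620 and AT2G43590, which had been seen, so they are not an independent test of the family. The result rests on 4 genes and cannot decide whether members elsewhere were higher. Cross-hybridization among related members was not tested and could contribute, and a response of these seedlings to their culture cannot be separated from the construct with 1 sample per group.

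Another hypothesis, that genes of branched-chain amino acid breakdown were higher together, came from IVD (1.65) and AT4G20930 (a bound of 1.71). The 7 measured members not looked at before had a median of 0.02, at percentile 55.82, with 4 positive and 3 negative. Among them were MCCA at -1.40, ETFQO at -1.14 as a bound, D2HGDH at 0.71 as a bound, ETFBETA at 0.62 and ALDH6B2 at 0.36. With 2 of these 7 at least 2-fold lower, the test argues against a rise of all of them together. It covered 7 of 11 such members, with an SD over genes of 0.84, so a rise of part of the pathway stays open.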
